A study of Homo sapiens with 12 samples.

How the data were processed

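RNA was measured in 12 libraries of natural killer (NK) cells isolated from the blood of 2 donors, named PB1 and PB2 in the sample titles. The cells carried Cas9 only or had TGFBR2 knocked out, and were kept alone, in direct co-culture with acute myeloid leukaemia (AML) cells, or with AML cells across a transwell. Per the labels' protocols, full-length cDNA was made by template switching from 10 ng of total RNA with a low-input SMART-Seq kit, fragmented enzymatically, turned into libraries with a KAPA HyperPlus kit and sequenced in paired reads of 100 nt on a NovaSeq. No molecular identifiers and no step that marks strand are named there. Counts are therefore reads after PCR rather than molecules, and reads of overlapping or antisense genes and of near-identical paralogs can be shared.

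Per the submitters' processing notes, FastQC, STAR and DESeq2 were used with the hg19 build; their versions and roles, and the program that estimated abundance, are not given in the sources used here. Each library has a table of 26760 gene entries with the columns expected count, TPM and FPKM, per the file headers. The expected counts deposited by the authors are estimates of reads per gene and need not be whole (13.3 to 18.3% of the values were not). The TPM deposited by the authors are scaled to transcript length and to the same sum in each library, and the FPKM deposited by the authors are scaled to transcript length and library size. The FPKM were not used. Of the entries, 20502 carry a symbol and a gene number, 29 a number only and 6229 a transcript identifier only, and 20372 of the 20531 numbers matched the reference gene table. Entries with a transcript identifier only held 1.84 to 4.31% of the counts. The reference in hand was GRCh38 with GENCODE 29, a different build from the files, so it gave gene names, gene types and transcript sequences only, and no coordinates are printed. XIST, TSIX and Y-linked genes were left out of every test and table.

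Groups came from the titles. The comparisons, the tests, the gene lists and the rule for naming genes were set before the data were examined. Expected counts were rounded to whole numbers, scaled with TMM factors and filtered with filterByExpr, which left 13664 genes (1363 without a symbol). All 12 libraries entered a single edgeR 4.0.16 quasi-likelihood fit (R 4.3.3) with a coefficient for each of the 5 groups and the labelled donor as a block. The fit had 6 residual degrees of freedom, a prior of 3.72 and a common biological coefficient of variation of 0.55. Each of 7 contrasts was adjusted by Benjamini-Hochberg at 0.05. Fold changes are log2 with their standard errors, and levels are counts scaled to the library total (CPM). The donor stays in the model because the groups hold the donors in unequal numbers: every Cas9 direct library is labelled PB2 and every transwell library PB1, so those contrasts rest on the donor term. As a check of the pairing by donor, deviations of the same-donor libraries in the 2 groups without AML cells correlated at -0.507 across 13664 genes. Same-donor libraries thus did not deviate alike, and this check does not bear out the pairing, which comes from the titles.

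Gene lists numbered 28. The list of mitochondrially encoded genes had 0 of its 13 members in the files and the platelet list had fewer than 3 tested members, which left 26. They covered TGF-beta response, the BATF and AP-1 family, inhibitory receptors and exhaustion, NK activating receptors, cytotoxic granules, effector cytokines, NK transcription factors, tissue residency, homing receptors, cytokine receptors, cell cycle, glycolysis, nuclear oxidative phosphorylation, hypoxia, interferon-stimulated genes, NF-kB targets, the integrated stress response, cholesterol synthesis, p53 targets, heat shock and early response, chromatin modifiers, and markers of AML blasts, monocytes, T cells, B cells and erythroid cells. Each list was tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Beside it stand camera with a correlation estimated per list, fry, and the number of members that pass when adjusted over the list alone. Where the text says that a list shifted up or down, camera passed with the preset correlation. With an estimated correlation 0 of the 37 such calls passed.

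The text names TGFBR2 and BATF in each comparison. In the edgeR fit no gene passed over all genes, so the part of the rule that names the 8 largest changes each way gave none. Of the 4 members with the smallest p that the rule allows for a list, the text names the first 2 of each list that shifted, the first of each other list if its unadjusted p was under 0.05, and any of the 4 that passed over the list alone. Where no list shifted, it names the first 2 of the list with the smallest p and of the TGF-beta list. This narrowing was chosen after the data were seen. Members that differ between the donors were not named (4 instances). Levels stand in place of fold changes for HBB, HBG2, CXCL10 and CCL22. Other named genes with a mean under 1 CPM in a compared group (IFI44L, IFIT1, CTLA4, BCL6, TCF7, CSF1R and CD5) keep their fitted fold change, which depends on the prior count.

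Libraries held 11626256 to 17483097 expected counts and 15405 to 17892 genes with a count, and the 10 most abundant genes took 7.9 to 11.9%. In the 9 pairs of replicates, chi-square per gene, which covers counting error only, was 102 to 289 and the Pearson r of log2 CPM was 0.87 to 0.936, so no pair looked like repeats of 1 library. The edgeR step was tested on simulated data for Cas9 direct against Cas9 alone, with 13373 genes of which 200 were changed. At 2-, 4-, 8- and 16-fold it called 0, 0, 28 and 56% of 50 changed genes each, with 1 of 13173 unchanged genes called. DESeq2 1.42.0 called 8, 20, 62 and 92%, with 61 unchanged genes called.

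Alternatives set beforehand were the fit without the donor block, DESeq2, RLE factors, no filter, limma-trend on log2(TPM + 1), the fit without transwell libraries, fits within each donor, camera with an estimated correlation, and 12 fits that each left out 1 library. A lone library left in a group is then assumed to vary like the other groups. The fits within each donor take the donor from the titles and hold 1 library of each group without AML cells. Alternatives chosen after seeing the data were a block by the donor side read from the data, a covariate for transcripts with a GC-rich stretch, both together, a covariate for the AML source in the titles (AML1 and AML2 at equal distances from 0, the library with no number left out), the fit without those transcripts, the fit without co-cultured libraries that lay on the side of the other donor, and a crossed pairing for the knockout alone against Cas9 alone. The covariate is the mean log2(CPM + 1), centred per gene, of 816 genes whose reference transcript holds a window of 150 nt with at least 80.0% G and C, the top 10% of the 7473 genes with a transcript among 7682 above 4 log2 CPM, minus that of 6655 other genes, with TGFBR2 and BATF in neither. It was chosen among 4 transcript properties compared with the first principal component of the libraries. Permutation tests, figures and GC values were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The design text lists samples that were not analysed here, and its combinations of donor and AML source differ from those of the titles.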

Results

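RNA was sequenced from natural killer (NK) cells of human blood, lymphocytes that kill tumour and infected cells. The cells carried Cas9 only, or Cas9 had been used to knock out TGFBR2, a chain of the receptor for the cytokine TGF-beta. They were cultured alone, in direct contact with acute myeloid leukaemia (AML) cells, or with AML cells behind a transwell membrane, which lets soluble factors pass. The 12 libraries formed 5 groups: Cas9 alone (n = 2), knockout alone (n = 2), Cas9 direct (n = 2), knockout direct (n = 3) and Cas9 transwell (n = 3). The titles gave 2 donors, PB1 and PB2. Each group without AML cells held 1 library of each donor. Both Cas9 direct libraries were labelled PB2 and all 3 transwell libraries PB1. The knockout direct group held 2 labelled PB1 and 1 labelled PB2. The AML cells came from 2 sources, AML1 and AML2, except that 1 transwell title gave no number. Nothing said whether replicates came from separate cultures, so p-values measure the spread between these libraries, which can be technical in part. Total expected counts, in replicate order, were 13365446 and 16745542 in Cas9 alone and 17483097 and 15818570 in knockout alone. They were 12514874 and 15645115 in Cas9 direct, 15025767, 16097651 and 13073951 in knockout direct, and 16396162, 13490834 and 11626256 in Cas9 transwell.

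TGFBR2, the targeted gene, was measured at 18.3 and 142 CPM in Cas9 alone replicates 1 and 2, and at 164 and 25.1 CPM in knockout alone replicates 1 and 2. In Cas9 direct it was 41.6 and 28.8 CPM, in knockout direct 116, 23.7 and 103 CPM, and in Cas9 transwell 319, 49.5 and 48.4 CPM. The 5 knockout libraries lay 0.15 log2 units above the 7 Cas9 libraries on average (two-sided exact permutation p = 0.842 over 792 splits). The level did not tell the groups apart, and an edited gene can still be transcribed. The directions below that involve the knockout therefore rest on the labels. Across the 12 libraries log2 TGFBR2 followed the mean level of 816 other genes whose transcripts hold a GC-rich stretch (Pearson r = 0.974, permutation p = 1e-05, the smallest that 100000 permutations can give, and Spearman rho = 0.958, permutation p = 2e-05). Without the 2 libraries farthest from the median of that score r was 0.967. Both relations were chosen after seeing the data. BATF, an AP-1 family transcription factor and the subject of the series, did not follow it (r = -0.124, permutation p = 0.7, rho = -0.21, permutation p = 0.51, and r = 0.314 without the 2 farthest libraries). BATF stood at 35.2 ± 3.85 CPM in Cas9 alone (SD, n = 2), 34.0 ± 2.78 in knockout alone (n = 2), 49.6 ± 17.3 in Cas9 direct (n = 2), 46.5 ± 14.5 in knockout direct (n = 3) and 40.9 ± 23.0 in Cas9 transwell (n = 3).

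**Figure D1:**
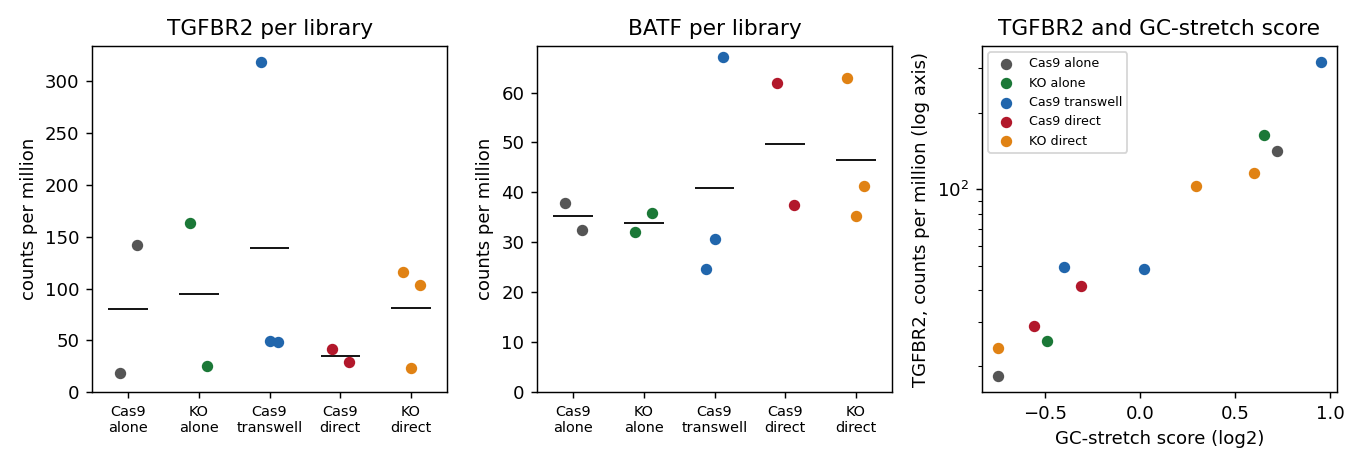
Level of TGFBR2 and of BATF in CPM for each of the 12 libraries by group, with a line at the group mean, and TGFBR2 in CPM on a log axis against the score of transcripts with a GC-rich stretch. TGFBR2 runs from 18.3 to 319 CPM with no order by group, and follows the score at r = 0.974.

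Neither gene passed in any of the 7 comparisons. By edgeR the adjusted p was 0.948 for BATF and 0.939 for TGFBR2 in Cas9 direct against transwell, and 1 for both genes in the other comparisons. For BATF the log2 fold change was 0.53 ± 0.60 (SE) in Cas9 direct against Cas9 alone, -0.01 ± 0.55 in Cas9 transwell against Cas9 alone and 0.53 ± 0.67 in Cas9 direct against transwell. It was -0.07 ± 0.56 in knockout against Cas9 alone, 0.32 ± 0.52 in knockout direct against knockout alone, and -0.27 ± 0.59 in knockout direct against Cas9 direct. For TGFBR2 the values in the same order were -1.31 ± 1.30, 0.90 ± 1.58, -2.21 ± 1.69, 0.46 ± 1.56, -0.44 ± 1.19 and 1.32 ± 1.40. The interaction of knockout and contact was -0.20 ± 0.82 for BATF and 0.86 ± 1.74 for TGFBR2.

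Cas9 direct was compared with Cas9 alone to show what contact with AML cells does to NK cells. Interferon-stimulated genes, which serve antiviral defence, were higher in contact. All 36 measured members had a positive fold change (median 2.16), and by edgeR 24 rose when adjusted over the list alone, against 0 over all genes. By DESeq2 16 members rose over all genes. IFI44L rose by 8.37 ± 1.26 log2 units (SE), from 0.374 ± 0.106 to 75.4 ± 56.2 CPM (SD, n = 2 each). MX1, a GTPase that restricts viruses, rose by 5.75 ± 0.94, from 22.9 ± 5.66 to 953 ± 972 CPM. IFI44 rose by 3.74 ± 0.63, from 8.48 ± 1.02 to 90.3 ± 15.3 CPM (adjusted p = 0.00121 over the list alone for each of the 3). The list shifted up with adjusted p = 1.95e-58 by camera, and adjusted p = 0.0727 with an estimated correlation.

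Further lists shifted in Cas9 direct against Cas9 alone, with 0 members passing over the list alone in each. Erythroid markers shifted up (5 of 8 members positive, adjusted p = 0.00124, and 0.225 with an estimated correlation). HBB, a haemoglobin chain, was at 0 CPM in the libraries without AML cells and at 1.81 ± 1.74 CPM in Cas9 direct. HBG2, a fetal haemoglobin chain, was at 0.0597 ± 0.0845 and 3.63 ± 4.14 CPM. Monocyte and macrophage markers shifted up (6 of 6, adjusted p = 0.0432, and 0.362 with an estimated correlation). CD68, a lysosomal protein of macrophages, was at 2.74 ± 1.07 and CSF1R, a macrophage growth factor receptor, at 1.63 ± 1.44. Inhibitory receptors shifted up (19 of 26, median 0.12, adjusted p = 0.0432, and 0.225 with an estimated correlation). The checkpoint receptor CTLA4 was at 5.91 ± 2.04, from 0.801 ± 0.879 to 28.7 ± 17.5 CPM, and the ectonucleotidase ENTPD1 at 1.27 ± 0.57. Targets of p53 shifted down (14 of 18 negative, median -0.47, adjusted p = 0.0224, and 0.225 with an estimated correlation). The mitochondrial reductase FDXR was at -1.18 ± 0.41 and PHLDA3, an inhibitor of AKT, at -3.52 ± 1.63. Members of other lists that did not pass were GZMM, a granzyme, at -1.69 ± 0.71, LEF1, a transcription factor of the Wnt pathway, at -2.12 ± 0.57, and the chemokine XCL1 at -1.90 ± 0.68. Nor did the chemokine receptor CCR1 at 1.70 ± 0.72, the IL-18 receptor chain IL18RAP at 1.20 ± 0.49, the DNA methyltransferase DNMT3A at -1.47 ± 0.56 and the ectoenzyme CD38 at 1.51 ± 0.48. CXCL10, a chemokine induced by interferon, was at 0.0374 ± 0.0529 CPM alone and 8.95 ± 11.3 CPM in contact.

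In this comparison edgeR called 0 genes (252 at unadjusted p under 0.05, lowest adjusted p = 0.38), limma-trend 0 and DESeq2 26, of which 22 were higher and 4 lower. Without any effect, a share of 0.05 of the 13664 genes would have an unadjusted p under 0.05. The unadjusted edgeR counts lay under that share here and in each other comparison of this fit, so they are no sign of change. Nor do 0 calls show that no gene changed. The interferon call stayed in all 12 fits that left out 1 library (highest adjusted p = 5.24e-20). Over the list alone 16 members rose without Cas9 alone replicate 1 or Cas9 direct replicate 2, and 14 within PB2. The p53 call was lost without Cas9 alone replicate 2 (adjusted p = 0.312), knockout alone replicate 1 (0.0524) or 2 (0.0557), or Cas9 direct replicate 2 (0.0738). PHLDA3 stood at 0.94 without Cas9 alone replicate 2. The erythroid call was lost without knockout direct replicate 3 (0.0736). The monocyte call was lost without knockout direct replicate 1 (0.175) or 3 (0.253) or Cas9 direct replicate 2 (0.0608), where CSF1R stood at -0.75. The call of the inhibitory receptors was lost without Cas9 alone replicate 2 (0.914), knockout alone replicate 1 (0.0524) or 2 (0.0585), knockout direct replicate 2 (0.056), or Cas9 direct replicate 1 (0.101) or 2 (0.179). Without the donor block the monocyte and inhibitory calls were lost (adjusted p = 0.12 and 0.326), and with RLE factors too (0.0797 each). With no filter the inhibitory and p53 calls were lost (0.0506 each). In fits chosen after seeing the data the inhibitory call was lost with the donor side read from the data as the block (0.435), and the inhibitory and monocyte calls with the GC-stretch score beside the labelled donor (0.156 each).

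Cas9 transwell was compared with Cas9 alone to show the effect of AML cells without contact. Here 34 of 36 interferon-stimulated genes had a positive fold change (median 1.99), and by edgeR 17 rose when adjusted over the list alone, against 0 over all genes. By DESeq2 13 members rose over all genes. MX1 rose by 5.00 ± 0.91 log2 units (SE), to 1111 ± 301 CPM (SD, n = 3). IFIT1, a protein that binds viral RNA, rose by 6.22 ± 1.21, from 1.25 ± 0.178 to 129 ± 60.3 CPM, and IFI44L by 6.06 ± 1.20 (adjusted p = 0.00479 over the list alone for each). The list shifted up with adjusted p = 1.94e-31 by camera, and adjusted p = 0.156 with an estimated correlation. Cell cycle genes shifted down, with 34 of 35 negative (median -0.90, adjusted p = 6.37e-13, and adjusted p = 0.0663 with an estimated correlation). By fry, which does not compare a list with other genes, this list passed in its comparison (adjusted p = 0.0426), and no other list did in any comparison. The spindle checkpoint kinase TTK stood at 56.8 ± 14.5 against 146 ± 2.69 CPM (-1.48 ± 0.44) and the mitotic kinase CDK1 at 181 ± 10.6 against 396 ± 8.67 CPM (-1.30 ± 0.39), neither passing over the list alone (adjusted p = 0.128).

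Genes of nuclear oxidative phosphorylation also shifted down in the transwell (28 of 31 negative, median -0.52, adjusted p = 3.86e-07, and 0.597 with an estimated correlation). The ATP synthase subunit ATP5F1C was at -1.20 ± 0.50 and the respiratory chain subunit COXFA4 at -1.27 ± 0.64. The mean log2(CPM + 1) of this list was 6.66 and 6.59 in transwell replicates 1 and 2 but 7.62 in replicate 3, above the 7.14 to 7.54 of the 4 libraries without AML cells. Cholesterol synthesis shifted down (18 of 20, median -0.51, adjusted p = 0.00105, and 0.585 with an estimated correlation). The synthase HMGCS1 fell by 1.76 log2 units (SE 0.43, adjusted p = 0.0437 over the list alone) and the squalene synthase FDFT1 was at -0.61 ± 0.35. Heat shock and early response genes shifted down (15 of 19, median -0.35, adjusted p = 0.00707, and 0.585 with an estimated correlation). RGS1, a regulator of G protein signalling, was at -2.39 ± 0.85 and the chaperone DNAJB1 at -0.80 ± 0.42. The integrated stress response shifted down (16 of 22, median -0.43, adjusted p = 0.00717, and 0.608 with an estimated correlation). The stress transcription factor DDIT3 was at -1.78 ± 0.68 and PHGDH, of serine synthesis, at -1.45 ± 0.70. Chromatin modifiers shifted up (16 of 25, median 0.45, adjusted p = 0.00707, and 0.585 with an estimated correlation). The DNA dioxygenase TET3 was at 1.51 ± 0.53 and the histone methyltransferase KMT2A at 1.30 ± 0.47. NK transcription factors shifted up (19 of 25, median 0.32, adjusted p = 0.0114, and 0.585 with an estimated correlation). The repressor BCL6 was at 1.92 ± 0.64 and TCF7 at 2.26 ± 1.24. From the remaining lists, the values were -0.97 ± 0.38 for KLF10, a TGF-beta inducible factor, -2.54 ± 0.86 for the AP-1 factor FOS, -1.55 ± 0.45 for the nuclear receptor NR4A2 and -2.38 ± 0.81 for the activation marker CD69. They were 1.36 ± 0.44 for the death ligand FASLG, -1.56 ± 0.61 for XCL1, -1.90 ± 0.58 for RGS2, 1.02 ± 0.44 for IL18RAP, -1.84 ± 0.61 for the NF-kB target IER3 and -1.24 ± 0.36 for FDXR, and none of these passed.

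For the transwell edgeR called 0 genes (495 at unadjusted p under 0.05, lowest adjusted p = 1), limma-trend 0 and DESeq2 22 (19 higher, 3 lower). The interferon, cell cycle and oxidative phosphorylation calls stayed in all 12 fits that left out 1 library (highest adjusted p = 1.54e-15, 1.2e-06 and 0.0105). Within PB1 22 interferon-stimulated genes rose over the list alone. Without Cas9 alone replicate 1, 0 did (edgeR), with MX1, IFIT1 and IFI44L at adjusted p = 0.103, 0.11 and 0.11. The call of HMGCS1 was lost without any 1 library (adjusted p = 0.053 to 0.66, highest without Cas9 alone replicate 1) except knockout alone replicate 2. It was also lost with no filter (0.0509), with limma-trend (0.141), within PB1 (0.28), and in fits chosen after seeing the data: with the AML source or the GC-stretch score beside the donor block (0.067 and 0.064), and with the donor side read from the data (0.0556). Without Cas9 alone replicate 1 the calls were lost for cholesterol synthesis (adjusted p = 0.157), heat shock (0.0784), chromatin modifiers (0.225) and NK transcription factors (0.182). The heat shock call was also lost without transwell replicate 1 (0.0662) or 2 (0.0502), and the chromatin call without knockout direct replicate 3 (0.0577). The call of NK transcription factors was also lost without transwell replicate 1 (0.11) or knockout direct replicate 3 (0.0727), and with no filter (0.054). The stress response call was lost without Cas9 alone replicate 2 (0.285), transwell replicate 2 (0.195) or knockout direct replicate 3 (0.0796).

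Cas9 direct was then set against Cas9 transwell, to separate contact from soluble factors. Cell cycle genes shifted up in contact (28 of 35 positive, median 0.99, adjusted p = 1.09e-09, and 0.126 with an estimated correlation). The cyclin CCNB1 was at 414 ± 174 against 135 ± 13.7 CPM (1.61 ± 0.47) and CDK1 at 1.67 ± 0.48. Oxidative phosphorylation genes shifted up (29 of 31, median 0.75, adjusted p = 3.39e-08, and 0.53 with an estimated correlation). ATP5F1C was at 1.30 ± 0.62 and the ATP synthase subunit ATP5PO at 1.41 ± 0.69. NR4A2 rose by 2.33 ± 0.55 log2 units (SE), at 25.3 ± 3.40 against 11.4 ± 4.82 CPM (adjusted p = 0.0487 over its list of inhibitory receptors alone). It was the only call over the list alone in this comparison. The integrated stress response also shifted up (16 of 22 positive, median 0.62, adjusted p = 0.00124), with PHGDH at 1.83 ± 0.84 and DDIT3 at 1.74 ± 0.84. So did cholesterol synthesis (15 of 20, median 0.47, adjusted p = 0.00904), with IDI1, an isoprenoid isomerase, at 1.16 ± 0.51 and FDFT1 at 0.89 ± 0.43. Erythroid markers shifted up (6 of 8, adjusted p = 0.0225), with the transferrin receptor TFRC at 0.93 ± 0.81 and HBB at 0 CPM in all transwell libraries. Chromatin modifiers shifted down (20 of 25 negative, median -0.85, adjusted p = 0.00241), with TET3 at -1.68 ± 0.60 and KMT2A at -1.37 ± 0.54. NK transcription factors did too (20 of 25, median -0.81, adjusted p = 0.0273), with LEF1 at -1.77 ± 0.65 and TCF7 at -2.98 ± 1.51. Each of these 5 lists stood at adjusted p = 0.53 with an estimated correlation. Interferon-stimulated genes shifted up by a median of 0.37 (28 of 36, adjusted p = 0.00212, and 0.773 with an estimated correlation). The antiviral genes IFIT2 and IFIT3 were at 2.28 ± 0.78 and 2.50 ± 1.14. There 0 members passed over the list alone.

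Other members did not pass in this comparison: CD69 stood at 2.57 ± 1.01, RGS1 at 3.80 ± 1.08, the granzyme GZMA at 1.33 ± 0.57, the chemokine receptor CX3CR1 at -1.66 ± 0.69, the lactate transporter SLC16A1 at 1.36 ± 0.56, the B cell scaffold BANK1 at 1.65 ± 0.64 and CSF1R at 3.80 ± 1.61. The means of CSF1R and of the chemokine CCL22 were under 1 CPM in both groups. edgeR called 0 genes (394 at unadjusted p under 0.05, lowest adjusted p = 0.94), limma-trend 0 and DESeq2 10 (5 higher, 5 lower). Both groups hold a single labelled donor each, so every value rests on the donor term. Without the donor block the interferon list turned down (adjusted p = 0.821). The call of NR4A2 was lost without any 1 library (adjusted p = 0.0586 to 0.202, highest without Cas9 alone replicate 1) except transwell replicate 1. It was also lost without the donor block (0.269), with limma-trend (0.386) and with the donor side read from the data (0.193, chosen after seeing the data). The interferon list was lost without Cas9 direct replicate 2 (adjusted p = 0.697) or knockout direct replicate 3 (0.537), and CD69 stood at -0.26 without Cas9 direct replicate 1. The cell cycle and oxidative phosphorylation calls stayed in all 12 fits that left out 1 library (highest adjusted p = 0.000627 and 0.00309). Lost were the stress response without Cas9 direct replicate 2 (0.117) or knockout direct replicate 3 (0.0859), and the chromatin modifiers without knockout direct replicate 3 (0.0851). Cholesterol synthesis was lost without transwell replicate 3 (0.134) or Cas9 direct replicate 2 (0.349), and with the AML source beside the donor block (0.118). The erythroid call was lost without knockout alone replicate 1 (0.0743) or 2 (0.0876), transwell replicate 2 (0.159), Cas9 direct replicate 1 (0.136) or knockout direct replicate 3 (0.254). That of NK transcription factors was lost without transwell replicate 1 (0.0637) or 2 (0.0613), knockout direct replicate 2 (0.0607) or 3 (0.254), or Cas9 direct replicate 1 (0.0627) or 2 (0.139).

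Libraries labelled knockout alone were compared with Cas9 alone for the effect of losing TGFBR2 without AML cells. No list shifted (lowest adjusted p = 0.198, for NK transcription factors, 20 of 25 positive, median 0.18). Genes of the TGF-beta response lay at a median of 0.02, with 14 positive and 12 negative (adjusted p = 0.551). Interferon-stimulated genes lay at -0.01, with 17 positive and 19 negative (adjusted p = 0.932). The cytokine TGFB1 stood at 277 ± 142 against 170 ± 135 CPM (SD, n = 2 each, log2 fold change 1.24 ± 0.99) and the integrin ITGA1 at 169 ± 70.0 against 125 ± 127 CPM (0.95 ± 0.95). The transcription factors GATA3 and ETS1 were at 0.89 ± 0.82 and 0.47 ± 0.55. edgeR called 0 genes (22 at unadjusted p under 0.05, lowest adjusted p = 1), limma-trend 0, and DESeq2 1 (uc002amj.2, a transcript identifier with no gene symbol, at a mean of 0.3 CPM, named after its values were seen). Without knockout alone replicate 1 TGFB1, ITGA1 and GATA3 turned to -0.72, -0.55 and -0.78. While no list passed with all 12 libraries, 4 did without knockout alone replicate 1, 4 without knockout alone replicate 2, 2 without Cas9 alone replicate 1 and 3 without Cas9 alone replicate 2. Within PB2 TGFB1, ITGA1, GATA3 and ETS1 stood at -0.67, -0.92, -0.69 and -0.11.

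Contact with AML cells was next examined in the libraries labelled knockout, direct against alone. Of the 36 interferon-stimulated genes 34 had a positive fold change (median 1.95), and by edgeR 21 rose when adjusted over the list alone, against 0 over all genes. By DESeq2 14 members rose over all genes. IFI44L rose by 7.56 ± 1.24 log2 units (SE), from 0.244 ± 0.102 (n = 2) to 83.7 ± 62.1 CPM (SD, n = 3). IFIT1 rose by 7.20 ± 1.25 and MX1 by 5.01 ± 0.88, from 25.4 ± 3.34 to 1053 ± 681 CPM (adjusted p = 0.00256 over the list alone for each), and IFI44 by 3.24 ± 0.59 (adjusted p = 0.00262). The list shifted up with adjusted p = 3.82e-46 by camera, and adjusted p = 0.13 with an estimated correlation. From lists that did not shift, 4 genes fell when adjusted over their list alone. FOS fell by 3.93 log2 units (SE 0.84), from 247 ± 25.3 to 18.5 ± 9.42 CPM (adjusted p = 0.0194). XCL1, a chemokine for dendritic cells, fell by 2.73 (SE 0.59), from 241 ± 32.6 to 40.1 ± 13.6 CPM (adjusted p = 0.0222 among effector cytokines and 0.0202 among residency genes). The kinase phosphatase DUSP6 fell by 1.40 (SE 0.37, adjusted p = 0.0356) and CD69 by 2.77 (SE 0.79), from 1158 ± 71.8 to 193 ± 44.4 CPM (adjusted p = 0.0393 among residency genes, 0.136 among activating receptors). The lists that hold them did not shift (adjusted p = 0.322 for the BATF and AP-1 family, 0.0535 for effector cytokines, 0.175 for residency and 0.25 for activating receptors).

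Heat shock and early response genes shifted down in this comparison (14 of 19 negative, median -0.52, adjusted p = 0.00406, and 0.316 with an estimated correlation). The transcription factor KLF6 was at -0.93 ± 0.32 and the mRNA decay factor ZFP36 at -1.82 ± 0.67. T cell markers shifted down (10 of 11, median -0.70, adjusted p = 0.00385, and 0.681 with an estimated correlation). The receptor CD5, under 2 CPM in both groups, was at -3.76 ± 1.39 and its relative CD6 at -3.61 ± 2.06. Erythroid markers shifted up (7 of 8, adjusted p = 3.79e-05, and 0.223 with an estimated correlation). HBB was at 0 CPM alone and 0.638 ± 0.391 CPM in contact and HBG2 at 0.0316 ± 0.0447 and 0.779 ± 0.257 CPM. Monocyte markers shifted up (6 of 6, median 1.38, adjusted p = 0.0191, and 0.316 with an estimated correlation). CD68 was at 2.53 ± 1.04 and CSF1R at 2.06 ± 1.33. From the other lists, the values were -2.54 ± 0.66 for the tetraspanin CD9, 3.92 ± 1.68 for CTLA4, -1.81 ± 0.59 for GZMM, 1.92 ± 0.62 for BCL6, -1.31 ± 0.52 for CX3CR1 and -1.27 ± 0.57 for the STAT5 target CISH. They were -2.21 ± 0.58 for IER3, -0.87 ± 0.35 for FDXR, 1.67 ± 0.62 for the histone demethylase KDM6B, 1.49 ± 0.43 for CD38 and -0.87 ± 0.39 for the B cell receptor component CD79B, none of which passed.

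edgeR called 0 genes here (326 at unadjusted p under 0.05, lowest adjusted p = 0.87), limma-trend 1 (uc010tmp.1, a transcript identifier with no gene symbol, -3.37, named after its values were seen), and DESeq2 28 (21 higher, 7 lower). The interferon and erythroid calls stayed in all 12 fits that left out 1 library (highest adjusted p = 1.04e-15 and 0.0248). Over the list alone 4 interferon-stimulated genes rose without knockout alone replicate 1, where IFI44 stood at adjusted p = 0.0735. Within PB1 the median log2 fold change of the list was 2.43, and within PB2 1.24. Each of these 2 fits holds 1 knockout alone library, and the PB2 fit 1 knockout direct library. They take the donor from the titles, which the donor check below goes against for all knockout direct libraries. FOS lost its call without knockout alone replicate 1 (adjusted p = 0.15) or 2 (0.0892) or knockout direct replicate 1 (0.0905) or 3 (0.155). XCL1 lost it among effector cytokines without knockout alone replicate 1 (0.119) or 2 (0.189) or knockout direct replicate 2 (0.0868) or 3 (0.196), and among residency genes at 0.108, 0.156, 0.09 and 0.116 without the same libraries. DUSP6 lost it without any knockout library (0.09 to 0.254), either Cas9 alone library (0.0612 and 0.0549) or transwell replicate 2 (0.0619). CD69 lost it without any 1 library (0.0549 to 0.199) except the 2 of Cas9 direct. Other fits ended these calls too. Without the transwell libraries the adjusted p was 0.0756 for FOS, 0.0685 for XCL1 among effector cytokines and 0.106 for CD69. Within PB1 it was 0.192 for FOS, 0.376 and 0.171 for XCL1 and 0.212 for both DUSP6 and CD69. Within PB2 it was 0.387 for FOS, 0.204 and 0.371 for XCL1 and 0.438 for both DUSP6 and CD69, with MX1 at 0.0623 and IFI44 at 0.135. With limma-trend DUSP6 and CD69 stood at 0.0512, and with no filter DUSP6 at 0.0616. With the AML source beside the donor block, chosen after seeing the data, FOS stood at 0.139 and CD69 at 0.141. The T cell call was lost without knockout alone replicate 1 (adjusted p = 0.13), where CD6 stood at 2.12, or 2 (0.0618). The heat shock call was lost without knockout alone replicate 2 (0.118), and the monocyte call without knockout alone replicate 1 (0.61) or knockout direct replicate 1 (0.217) or 2 (0.0736), and with no filter (0.55).

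**Figure D2:**
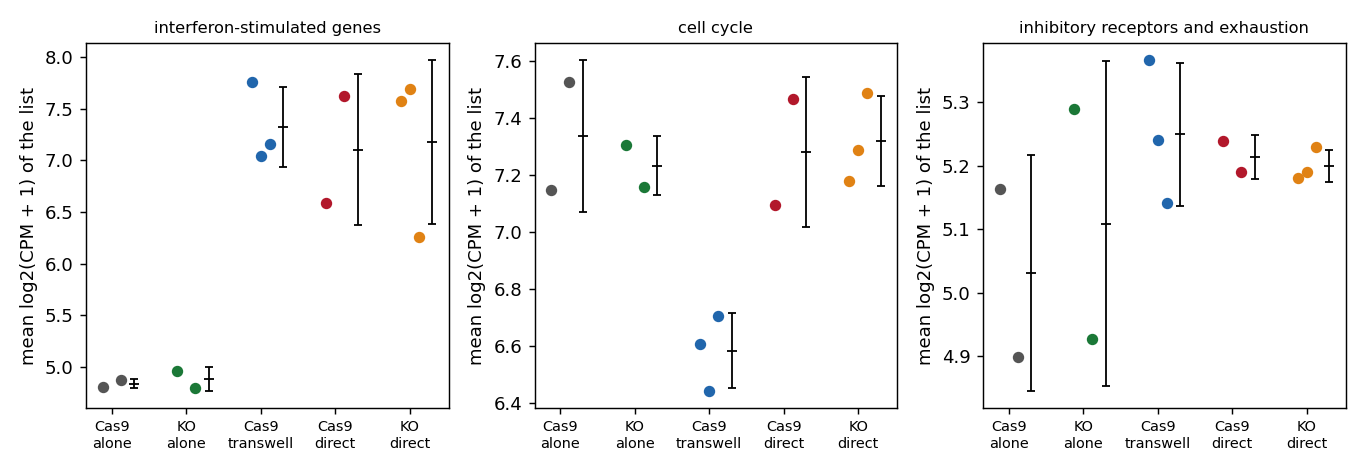
Mean log2(CPM + 1) of the interferon-stimulated, cell cycle and inhibitory receptor lists in each library by group, as points with the group mean and SD. For interferon-stimulated genes all 8 co-cultured libraries lie above all 4 libraries without AML cells.

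In a test chosen after seeing the data, the mean log2(CPM + 1) of each list was compared between the 8 co-cultured and the 4 other libraries. Interferon-stimulated genes were 2.35 higher in co-culture, each of the 8 above each of the 4 (two-sided exact permutation p = 0.00202, the smallest that 495 splits allow, adjusted p = 0.0263 over 26 lists). Monocyte markers were 0.57 higher at the same p. Of the 36 interferon-stimulated genes, 23 were higher in all 8 than in all 4, where chance gives 0.2%. Across 13664 genes, which are not independent replicates, the fold changes of contact in Cas9 and in knockout cells correlated at r = 0.458 (covariance 0.384), beside -0.046 (covariance -0.042) over 20 simulated sets without group effects. At unadjusted p under 0.05, 71 genes were higher and 39 lower in both, where independent lists would share 1.9 and 1.1, and the simulated sets 13.7 and 10.6. Direct contact and transwell in Cas9 cells correlated at 0.313 (covariance 0.282), which is under the simulated 0.353 (covariance 0.349) that their shared control libraries and donor term give. It was under the simulated value also without the donor block (0.403 against 0.554) and with the donor side read from the data as the block (0.465 against 0.55). Here 45 genes were higher and 8 lower in both (2.6 and 1.9 for independent lists, 72.3 and 23 simulated). The simulated sets drew each gene independently. They lack variation that many genes share within a library, such as the first component of the libraries, which held 51.2% of the variance. For both pairs of comparisons they therefore set no bound on the r or the shared counts that such variation can give. The Cas9 alone group holds 2 libraries and could not be divided between the comparisons, so part of any overlap can come from the shared controls.

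Libraries labelled knockout direct were compared with Cas9 direct for the effect of the knockout during contact. The activation marker CD69 stood at 193 ± 44.4 CPM (n = 3) against 1324 ± 1600 CPM (SD, n = 2), at -3.13 ± 0.94 log2 units (SE). IFNG, the NK cell's main interferon, was at 144 ± 57.5 against 1091 ± 1317 CPM (-3.47 ± 1.63). Both means rest on Cas9 direct replicate 1, with 2455 CPM of CD69 and 2022 CPM of IFNG, and neither gene passed over its list alone. Without that library CD69 stood at -0.33, RGS1 at -0.32 and FOS at -0.75. Interferon-stimulated genes shifted down (30 of 36 negative, median -0.32, adjusted p = 0.000389), with IFIT2 at -2.01 ± 0.73. This shift of the list rests on the labelled donor term. The median was 0.071 without the donor block and -0.036 with the donor side read from the data. The group means of log2(CPM + 1) were 7.175 in knockout direct and 7.102 in Cas9 direct. Oxidative phosphorylation shifted down too (24 of 31 negative, median -0.47, adjusted p = 0.00223), with ATP5PO at -0.92 ± 0.62 and ATP5F1C at -0.83 ± 0.56. The mean log2(CPM + 1) of that list was 7.96 and 7.78 in the Cas9 and knockout direct libraries with AML1, and 7.18 in Cas9 direct and 7.16 and 7.15 in knockout direct with AML2. Activating receptors shifted down (16 of 23, median -0.24, adjusted p = 0.0106), with the receptor KLRF1 at -1.23 ± 0.72, and so did effector cytokines (17 of 22, median -0.72, adjusted p = 0.0153). Residency genes shifted down (12 of 20, median -0.18, adjusted p = 0.0351), with RGS1 at -2.93 ± 0.97. Inhibitory receptors did too (15 of 26, median -0.23, adjusted p = 0.0351), with NR4A2 at -1.17 ± 0.48 and its relative NR4A1 at -1.55 ± 0.78. Chromatin modifiers shifted up (20 of 25, median 0.44, adjusted p = 0.00954). The remodelling subunit ARID1A was at 1.02 ± 0.47 and TET3 at 0.96 ± 0.53. With an estimated correlation the adjusted p was 0.832 for oxidative phosphorylation and 0.706 for each of the other 6. FOS stood at -3.46 ± 0.98 and IER3 at -2.02 ± 0.68, and CXCL10 at 1.19 ± 0.528 against 8.95 ± 11.3 CPM.

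edgeR called 0 genes between the direct groups (43 at unadjusted p under 0.05, lowest adjusted p = 1), limma-trend 0, and DESeq2 3 (uc001wfe.2, uc002amj.2 and uc010ven.1, transcript identifiers with no gene symbol and means of 0.46, 0.3 and 0.41 CPM, named after their values were seen). None of the 7 lists kept its call in all fits that left out 1 library. The interferon list was lost without Cas9 direct replicate 2 (adjusted p = 0.999) and turned up without knockout direct replicate 3 (0.0359). Oxidative phosphorylation was lost without Cas9 direct replicate 1 (0.707, turned up, with ATP5PO at 0.10) or knockout direct replicate 3 (0.831). Without Cas9 direct replicate 1 the activating receptors (0.707) and residency genes (0.584) turned up. The calls of effector cytokines (0.706), inhibitory receptors (0.137) and chromatin modifiers (0.137) were lost there. Chromatin modifiers were also lost without Cas9 direct replicate 2 (0.0548) or knockout direct replicate 3 (0.799), and effector cytokines without knockout direct replicate 2 (0.0914) or 3 (0.493). Activating receptors were also lost without Cas9 alone replicate 1 (0.139) or 2 (0.118) or knockout direct replicate 2 (0.0627). Residency genes were lost without Cas9 alone replicate 1 (0.0595) or 2 (0.0605), knockout alone replicate 1 (0.204) or 2 (0.225), or knockout direct replicate 2 (0.176). Inhibitory receptors were lost without Cas9 alone replicate 1 (0.125) or 2 (0.118), knockout alone replicate 1 (0.0706) or 2 (0.0805), knockout direct replicate 1 (0.105) or 2 (0.0627), or Cas9 direct replicate 2 (0.187). Without the donor block the adjusted p was 0.682 for interferon-stimulated genes, 0.0825 for chromatin modifiers, 0.185 for activating receptors, 0.299 for effector cytokines and 0.434 for inhibitory receptors. With RLE factors inhibitory receptors (0.0582) and residency genes (0.0591) were lost. Of the direct libraries, 1 of 2 with Cas9 and 1 of 3 with the knockout had AML1. With the AML source beside the donor block, chosen after seeing the data, 4 of 7 calls held, and those of oxidative phosphorylation (0.0527), activating receptors (0.158) and residency genes (0.185) were lost. With the donor side read from the data as the block, also chosen after, all but oxidative phosphorylation were lost. There the adjusted p was 0.433 for interferon-stimulated genes, 0.43 for activating receptors, 0.143 for effector cytokines, 0.101 for residency genes, 0.433 for inhibitory receptors and 0.0517 for chromatin modifiers.

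The interaction asked whether the response to contact differed between libraries labelled knockout and Cas9. Of 26 lists 4 shifted down, that is, the change on contact was lower in the knockout, be it a smaller rise or a larger fall. They were interferon-stimulated genes (28 of 36 negative, median -0.31, adjusted p = 0.000586, and 0.778 with an estimated correlation) and inhibitory receptors (17 of 26, median -0.37, adjusted p = 0.0196, and 0.315). The others were activating receptors (15 of 23, median -0.21, adjusted p = 0.0336, and 0.778) and effector cytokines (16 of 22, median -0.62, adjusted p = 0.0336, and 0.778). Between group means of log2(CPM + 1), without the donor term, interferon-stimulated genes went from 4.839 to 7.102 in Cas9 and from 4.881 to 7.175 in the knockout. Inhibitory receptors went from 5.031 to 5.214 and from 5.109 to 5.200. Activating receptors went from 7.659 to 7.610 and from 7.672 to 7.465, and effector cytokines from 5.194 to 5.170 and from 5.226 to 4.909, so these 2 lists fell further in the knockout. NR4A2 stood at -1.50 ± 0.66 log2 units (SE), NR4A1 at -1.47 ± 1.10, and CD69 at -2.96 ± 1.27, with -0.17 for CD69 without Cas9 direct replicate 1. The receptor KLRK1 was at -0.84 ± 0.82, IFNG at -3.34 ± 2.20, IFIT2 at -2.11 ± 0.96 and FOS at -3.16 ± 1.30. In the interaction 0 members of any list passed over the list alone. CXCL10 was under 0.3 CPM in every library without AML cells. edgeR called 0 genes (39 at unadjusted p under 0.05, lowest adjusted p = 1), limma-trend 0, and DESeq2 the same 3 transcript identifiers as between the direct groups. Without the donor block 0 of the 4 passed (adjusted p = 0.745, 0.383, 0.383 and 0.437), and the median of the interferon list was 0.035. With the donor side read from the data as the block, chosen after seeing the data, 0 passed either (0.485, 0.344, 0.502 and 0.344), and that median was 0.053. With the AML source beside the donor block activating receptors (0.207) and effector cytokines (0.0984) were lost, and effector cytokines with RLE factors (0.0881) or no filter (0.071).

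Each of the 4 interaction calls was lost without some libraries. The interferon list was lost without Cas9 alone replicate 1 (adjusted p = 0.0903), knockout alone replicate 2 (0.275) or Cas9 direct replicate 2 (0.96), and turned up without knockout direct replicate 3 (0.0735). Inhibitory receptors were lost without Cas9 alone replicate 2 (0.812), knockout alone replicate 1 (0.089) or 2 (0.0945), or Cas9 direct replicate 1 (0.0966) or 2 (0.101). Activating receptors were lost without knockout alone replicate 2 (0.255) or knockout direct replicate 2 (0.141), and turned up without Cas9 alone replicate 2 (0.601) or Cas9 direct replicate 1 (0.666), where KLRK1 stood at 0.35. Effector cytokines were lost without Cas9 alone replicate 1 (0.131) or 2 (0.196), knockout alone replicate 2 (0.227), knockout direct replicate 2 (0.141) or 3 (0.551), or Cas9 direct replicate 1 (0.688).

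**Figure D3:**
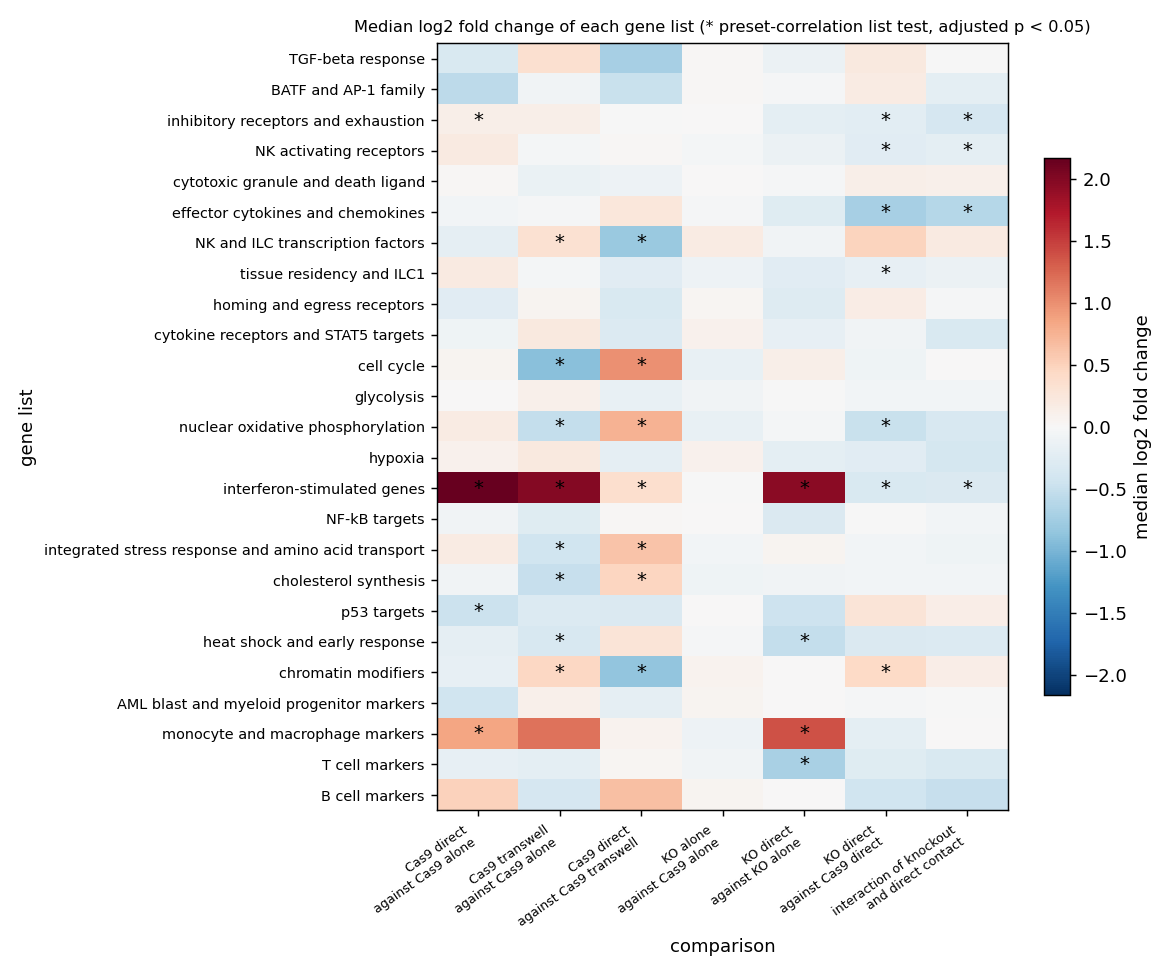
Median log2 fold change of the members of each gene list (one line per list) in the 7 comparisons (columns), on a colour scale, with an asterisk where camera gave an adjusted p under 0.05 (erythroid markers left out, as members lie near 0 CPM). The list of interferon-stimulated genes has medians of 2.16, 1.99 and 1.95 in the comparisons of direct Cas9, transwell Cas9 and direct knockout cells with cells alone.

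Of the 26 lists, 10 shifted in no comparison (lowest adjusted p = 0.115). The lowest adjusted p over the 7 comparisons was 0.454 for the TGF-beta response, 0.283 for the BATF and AP-1 family, 0.679 for cytotoxic granules and death ligands, and 0.508 for homing receptors. It was 0.155 for cytokine receptors and STAT5 targets, 0.507 for glycolysis, 0.12 for hypoxia, 0.123 for NF-kB targets, 0.413 for markers of AML blasts and 0.115 for B cell markers.

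The donor labels were checked with 63 genes that part PB1 from PB2 in the 4 libraries without AML cells. Of the 8 co-cultured libraries, 3 lay on the side of their labelled donor and 5 on the other side. All knockout direct libraries were among these 5, so no comparison with that group could be run without them. For that whole group the labelled donor block goes against this check. By this check 5 libraries did not match their labels, if the titles of the 4 libraries without AML cells are right. The check cannot test those 4 titles: with the donors crossed, 956 genes part by as wide a gap. Causes other than the titles stay open. In the 4 comparisons that kept both groups without these 5 libraries, edgeR again called 0 genes (33 to 1328 at unadjusted p under 0.05). With the side read from the data as the block in place of the label, the interferon list kept its call in Cas9 direct, Cas9 transwell and knockout direct against cells alone, with 23, 23 and 22 members rising over the list alone.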

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

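The tests of the interaction were set before the data were examined, while the fits with a donor side read from the data, with the GC-stretch score and with the AML source were chosen after the results were seen. A result stands here because the response to AML contact differed between the libraries labelled Cas9 and those labelled knockout by the interaction term of the model, tested on gene lists.

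Interferon-stimulated genes had a lower change in the knockout by the model with the labelled donor (camera adjusted p = 0.000586, median interaction -0.31, 28 of 36 members negative). The median was 0.035 without the donor block and 0.053 with the donor side read from the data as the block (adjusted p = 0.485), and the group mean scores rose from 4.839 to 7.102 in Cas9 and from 4.881 to 7.175 in the knockout. The adjusted p had a range of 4.03e-11 to 0.96 over the 12 fits that left out 1 library. Inhibitory receptors also had a lower change, at adjusted p = 0.0196 (median -0.37, 17 of 26 negative), with a range of 0.00559 to 0.812 over those fits, highest without Cas9 alone replicate 2. Activating receptors and effector cytokines had a negative interaction at adjusted p = 0.0336 each (medians -0.21 and -0.62, 15 of 23 and 16 of 22 negative), with ranges of 0.000119 to 0.666 and 0.00559 to 0.688, both highest without Cas9 direct replicate 1. Their group mean scores fell by contact from 7.672 to 7.465 and from 5.226 to 4.909 in the knockout, and from 7.659 to 7.610 and from 5.194 to 5.170 in Cas9. The interferon list turned up without knockout direct replicate 3 (0.0735), and activating receptors without Cas9 alone replicate 2 (0.601) or Cas9 direct replicate 1. With the donor side as the block inhibitory receptors, activating receptors and effector cytokines stood at 0.344, 0.502 and 0.344, and with the GC-stretch score beside the labelled donor block at 0.109, 0.197 and 0.13. With the AML source beside that block activating receptors and effector cytokines stood at 0.207 and 0.0984. Without the donor block the 4 lists stood at 0.745, 0.383, 0.383 and 0.437, and effector cytokines at 0.0881 with RLE factors and 0.071 with no filter. Cas9 direct replicate 1 held 2455 CPM of CD69, 836 CPM of RGS1, 280 CPM of FOS and 2022 CPM of IFNG. With an estimated correlation the 4 adjusted p-values were 0.778, 0.315, 0.778 and 0.778, and edgeR called 0 genes for the interaction (39 at unadjusted p under 0.05, DESeq2 3, limma-trend 0). The lower change of interferon-stimulated genes rested on the labelled donor term, since its median was 0.035 without that block and 0.053 with the donor side. By the donor check all knockout direct libraries lay on the side opposite to their label. It is therefore not evidence of a differing response. Beyond that, no explanation was tested for these 4 results.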

How the results depend on the processing

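Fits with a donor side read from the data, with the GC-stretch score, with the AML source of the titles (the library with no number left out), without genes with a GC-rich stretch, without libraries off their label and with a crossed pairing were chosen after the data were seen; the others were set before. In edgeR 0 genes passed in each of the 7 comparisons with the donor block (22 to 495 at unadjusted p under 0.05), without it, with RLE factors, with the AML source and in each of the 12 fits that left out 1 library. The same held in the 5 comparisons that could be run without transwell libraries (18 to 326), the 3 within PB1 and the 5 within PB2. The interferon list kept its call and direction in Cas9 direct, Cas9 transwell and knockout direct against cells alone in every alternative fit tested by camera with the preset correlation. It did not pass there with the estimated correlation, nor by fry (adjusted p = 0.0798, 0.0737 and 0.0891). Of the 37 list calls, 25 held without the donor block, 32 with RLE factors, 32 with no filter, 31 with the AML source, 25 with the GC-stretch score and 25 with the donor side read from the data. The cause of the changes below was not tested. No alternative varied the depth, so its limit on the calls was not measured. On simulated data at this size edgeR called 28 and 56% of genes changed 8- and 16-fold, and 0% of those changed 2- and 4-fold. With the labelled donor block the 22 to 495 genes at unadjusted p under 0.05 are each under a share of 0.05 of the 13664 tested. That share would be reached without any effect. These counts are therefore no sign of change, and 0 calls do not show its absence. Why the counts are so low was not tested.

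DESeq2 called 26, 22, 10, 1, 28, 3 and 3 genes, in the order Cas9 direct against alone, transwell against alone, direct against transwell, knockout against Cas9 alone, knockout direct against alone, knockout against Cas9 direct, and interaction. Of the 26, 22 and 28 called against cells alone, 16, 13 and 14 were members of the interferon list that rose. With no filter edgeR called 7, 3 (IFI44L, IFIT1 and MX1) and 6 in Cas9 direct, transwell and knockout direct against alone, all induced by interferon except FOS in the last, and limma-trend on log2(TPM + 1) 1 (uc010tmp.1) in knockout direct against alone; these were named after their values were seen. Lists past the threshold in Cas9 direct against alone fell in number from 5 to 3 without the donor block, with RLE factors, with no filter, with the GC-stretch score with either block, and without genes with a GC-rich stretch. Without the donor block 2 lists passed in knockout against Cas9 direct and 0 in the interaction. The interferon list then stood at adjusted p = 0.821 (turned down) in direct against transwell. It stood at 0.682 in knockout against Cas9 direct (median 0.071, from -0.321 with the block) and 0.745 in the interaction (median 0.035, from -0.312). With the donor side as the block these were 2 and 0 lists, and adjusted p = 0.619 (turned down), 0.433 and 0.485. With the donor side and the GC-stretch score they were 1 and 0 lists, and adjusted p = 0.516 (turned down), 0.59 and 0.717, and 5 lists passed in direct against transwell. With the labelled donor block and the GC-stretch score 5 lists passed in direct against transwell, 3 in knockout against Cas9 direct and 1 in the interaction, and without genes with a GC-rich stretch 1 in the interaction. With the AML source beside the donor block 4 lists passed in knockout against Cas9 direct and 2 in the interaction, where BATF turned to 0.01. With an estimated correlation 0 lists passed in any comparison, and the interferon list stood at adjusted p = 0.0727, 0.156, 0.773, 0.13, 0.706 and 0.778 in the 6 comparisons in which it had shifted. Without libraries off their label 10 lists passed in 1 of the 4 comparisons that kept both groups, and CD69 turned to -0.56 in another. The correlation of fold changes moved from 0.458 to 0.419 between contact in Cas9 and knockout cells with the donor side as the block, and from 0.313 to 0.403 (no block) or 0.465 (donor side) between contact and transwell, under the simulated 0.353, 0.554 and 0.55 each time. Those simulated sets hold no variation shared between genes within a library, so they set no bound on these values.

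Genes named that turned sign were as follows, as log2 fold changes that had not passed. BATF in transwell against alone was 0.06 without the donor block, 0.07 with DESeq2, 0.07 with RLE factors, 0.02 with no filter, 0.16 with limma-trend, 0.04 with the donor side as the block, with or without the GC-stretch score, and 0.04 without genes with a GC-rich stretch. TGFBR2 with the labelled donor block and the GC-stretch score was 0.30 in Cas9 direct against alone, 0.03 in direct against transwell, 0.01 in knockout direct against alone, -0.17 in knockout against Cas9 direct and -0.29 in the interaction. With the donor side and the score they were 0.23, 0.00, 0.07, -0.06 and -0.16. TGFBR2 was also 0.08 with limma-trend and 0.01 with the donor side in knockout direct against alone, and -0.36 with the donor side in knockout against Cas9 alone. Within PB2, in knockout against Cas9 alone, TGFBR2 was -2.58, BATF 0.07, TGFB1 -0.67, ITGA1 -0.92, GATA3 -0.69 and ETS1 -0.11, and in knockout direct against alone TGFBR2 was 1.90 and CD6 2.41.

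Leaving out 1 library gave these ranges of log2 fold change. In Cas9 direct against alone they were -1.99 (without Cas9 alone replicate 1) to 1.65 (without Cas9 alone replicate 2) for TGFBR2, -4.33 to 0.94 for PHLDA3 (the same libraries) and -0.75 to 2.80 for CSF1R (without Cas9 direct replicate 2, Cas9 alone replicate 1). In transwell against alone they were -0.76 to 2.78 for TGFBR2 (Cas9 alone replicates 1 and 2) and -0.60 to 0.26 for BATF (transwell replicates 3 and 1), and in direct against transwell -0.26 to 3.47 for CD69 (Cas9 direct replicates 1 and 2). In knockout against Cas9 alone they were -2.04 to 2.51 for TGFBR2, -0.28 to 0.12 for BATF, -0.72 to 2.41 for TGFB1, -0.55 to 2.20 for ITGA1 and -0.78 to 1.94 for GATA3, with the turned sign without knockout alone replicate 1 in each. In knockout direct against alone they were -1.61 to 2.75 for TGFBR2 and -5.20 to 2.12 for CD6, turned without knockout alone replicate 1. In knockout against Cas9 direct they were -0.61 to 0.15 for BATF, -1.52 to 0.10 for ATP5PO and -1.37 to 0.00 for ATP5F1C, and in the interaction -0.54 to 0.21 for BATF and -1.49 to 0.35 for KLRK1, all turned without Cas9 direct replicate 1. In the interaction TGFBR2 ran from -1.78 (without Cas9 alone replicate 2) to 4.31 (without knockout alone replicate 1).

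Leaving out 1 library gave 3 to 9 lists in Cas9 direct against alone (without knockout direct replicate 3, Cas9 direct replicate 1), 4 to 10 in transwell against alone (Cas9 alone replicate 1, transwell replicate 3), 4 to 9 in direct against transwell (knockout direct replicate 3, transwell replicate 3 or knockout direct replicate 1), 0 to 4 in knockout against Cas9 alone (4 without either knockout alone library), 3 to 7 in knockout direct against alone (fewest without knockout alone replicate 2), 1 to 9 in knockout against Cas9 direct (Cas9 direct replicate 1, knockout direct replicate 3) and 0 to 6 in the interaction (knockout alone replicate 2, Cas9 direct replicate 2). The adjusted p of the interferon list ran from 9.55e-10 to 0.697 in direct against transwell, 6.1e-13 to 0.999 in knockout against Cas9 direct and 4.03e-11 to 0.96 in the interaction, lowest without Cas9 direct replicate 1 and highest without replicate 2. In knockout against Cas9 direct it ran from 6.18e-05 to 0.707 for activating receptors, 8.48e-05 to 0.584 for residency genes and 2.43e-05 to 0.831 for oxidative phosphorylation, and in the interaction from 0.000119 to 0.666 for activating receptors.

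Lists lost with the labelled donor block and the GC-stretch score were, beside those of Cas9 direct against alone and of the interaction, NK transcription factors (adjusted p = 0.223), cholesterol synthesis (0.182) and chromatin modifiers (0.0871) in direct against transwell. In knockout against Cas9 direct they were inhibitory receptors (0.196), activating receptors (0.0822), effector cytokines (0.0632) and chromatin modifiers (0.0822). Without genes with a GC-rich stretch the calls lost were inhibitory receptors (0.201) and monocyte markers (0.0923) in Cas9 direct against alone, NK transcription factors (0.156) in direct against transwell, inhibitory receptors and residency genes (0.107 each) in knockout against Cas9 direct, and inhibitory receptors (0.0615), activating receptors (0.0926) and effector cytokines (0.0762) in the interaction.

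The donor block pairs the libraries by the donor in the titles. In the 2 groups without AML cells same-donor libraries deviated apart (correlation -0.507), and a crossed pairing as the replicate block gave 0 genes in knockout against Cas9 alone (28 at unadjusted p under 0.05). The GC-stretch score ran opposite ways in the labelled pairs. It was -0.743 in Cas9 alone replicate 1 and 0.650 in knockout alone replicate 1, and 0.720 and -0.487 in replicate 2 of the same groups. Within a donor no fit could be made for comparisons in which that donor lacks a group, and list tests were not run within donors or without transwell libraries.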

Other observations

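The genes of the first 2 paragraphs were chosen after their values were seen, and so were the tests of the AML source, of transcripts with a GC-rich stretch, of library depth, of TGFBR2 loss, of myeloid RNA and of the donor labels. The edgeR and DESeq2 comparisons and the count of interferon-stimulated genes in the model with the labelled donor were set beforehand. CD86, a costimulatory ligand of CD28 and CTLA4, ran from 71.6 to 132 CPM in the 5 direct libraries, against 17.3 to 21.0 CPM in the 4 without AML cells and 19.7 to 31.5 CPM in the 3 transwell libraries. Its log2 fold change was 2.74 ± 0.47 (SE) in Cas9 direct against alone, 2.74 ± 0.51 against transwell and 2.26 ± 0.43 in the knockout, at adjusted p = 0.382, 0.939 and 0.869 by edgeR and 2.5e-06, 0.000531 and 6.17e-05 by DESeq2. CTLA4, a receptor for CD86, ran from 11.3 to 41.0 CPM in direct libraries and up to 1.42 CPM without AML cells, and was 0.24, 0.37 and 15.0 CPM in the transwell. KIT, the stem cell factor receptor, ran from 51.8 to 161 CPM in direct libraries, against 241 to 283 CPM without AML cells and 190 to 322 CPM in the transwell.

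The sum of 7 haemoglobin genes was 2.11 to 18.8 CPM in direct libraries, 0, 0.06 and 5.16 CPM in the transwell and up to 0.3 CPM without AML cells. The granzyme GZMB was 687, 886 and 5500 CPM in the 3 transwell libraries, 1050 to 4070 CPM in direct libraries and 938 to 1693 CPM without AML cells. Between AML sources, in the 11 libraries with a known source or none, edgeR called 0 genes (945 at unadjusted p under 0.05, 4 residual degrees of freedom; no other tool was run on this contrast). By camera 5 lists shifted, and 0 did with an estimated correlation. Oxidative phosphorylation (median -0.51 for AML2 against AML1, adjusted p = 1.85e-05), effector cytokines (-0.43, 0.0127) and activating receptors (-0.31, 0.0254) were lower with AML2, and homing receptors (0.55, 0.00517) and interferon-stimulated genes (0.32, 0.0127) higher. These directions did not hold in every library. In the transwell the mean log2(CPM + 1) of oxidative phosphorylation was 6.66 with AML2 and 6.59 with AML1, while in direct libraries it was lower with AML2. That of interferon-stimulated genes in knockout direct was 7.57 with AML1, and 7.69 and 6.26 with AML2. No fit left out 1 library for this contrast. BATF was at -0.61 ± 0.26 (SE, adjusted p = 0.653), with 61.9 and 62.9 CPM in the direct libraries with AML1 and 35.3 to 41.2 CPM in the 3 with AML2. In the transwell it was 30.8 CPM with AML1 and 24.8 CPM with AML2. IFNG ran from 77.6 to 2022 CPM in direct libraries, was 72.5, 97.7 and 1583 CPM in the transwell, and was 180 to 269 CPM without AML cells.

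TGFBR2 ranged from 18.3 to 319 CPM with wide gaps inside groups. Loss of its mRNA in the knockout is argued against, since with the GC-stretch score fitted out knockout libraries lay at -0.071 log2 units from Cas9 libraries (two-sided exact permutation p = 0.682). After the same step r with the library total was 0.126, which argues against depth only where it acts apart from the score. The step removes any effect of depth through the score, so that part stays open. Uneven recovery of transcripts with a GC-rich stretch may account for the gaps, since TGFBR2 followed the score of other such genes at r = 0.974 and its transcript holds a window of 81.3% GC (92.4th percentile) within 47.4% as a whole. That stretch was the strongest of 4 properties compared with the first component of the libraries, which held 51.2% of the variance (Spearman across genes 0.467, against 0.157 for whole-transcript GC, 0.376 for the first 500 nt and -0.155 for length). A difference in TGFBR2 between the cells themselves stays open, as the design gives no measure of it.

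Interferon-stimulated genes were higher in all 8 co-cultured libraries than in all 4 others. RNA of AML or myeloid cells is argued against, since 46 of their markers that NK cells hardly express rose by 17.0 CPM in sum (2.57 without CD68), 0.22% of the 7593 CPM of the interferon-stimulated genes. Uneven recovery of GC-rich transcripts and the donor labels are argued against too, since 28 members passed over the list alone in Cas9 direct against alone with the GC-stretch score and 23 with the donor side from the data, against 24 in the model with the labelled donor. A response of the NK cells to AML cells or their soluble factors is therefore a hypothesis that these tests leave standing, found and tested on the same libraries. Differences in culture between the libraries with and without AML cells were not described and stay open.

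Of the 8 co-cultured libraries 5 lay on the side of the other donor by 63 genes, with 7.9 to 28.6% of these on the labelled side, and as many by the 25 genes with the wider gap. RNA of another person's cells mixed in as the smaller part is argued against, since in each of the 5 at least 66.7% of the genes high in the labelled donor lay below the midpoint. A mix in which the other RNA is the larger part could also put them there, so it stays open. A change of these genes by co-culture alike in every library is argued against, since only 4.8% of the 63 genes lay on 1 side in all 8 co-cultured libraries or all but 1, and 4 libraries lay on each side. A change by co-culture that differs between libraries was not tested and stays open. Titles that give another donor than that of the NK cells may be the cause. At most 31.6% of 38 held-out genes lay on the labelled side. Those genes were chosen in the same 4 libraries and read in the same co-cultured libraries as the 25. The value therefore cannot tell this cause from the others that stay open. The check takes the 4 titles without AML cells as right, and the crossed split of those 4 parts 956 genes, of which 952 are higher in the pair with the higher GC-stretch score. A further donor stays open, as does an error in the titles of the libraries without AML cells.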
